A study of Mus musculus with 12 samples.

How the data were processed

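The data were expression values of mouse cumulus cells from 12 microarrays, 4 for each of 3 culture conditions. Per the labels, cumulus-oocyte complexes came from 129SV females aged 21 to 26 days, 44 h after an injection of 5 IU equine chorionic gonadotropin. The complexes were collected in medium with cilostamide, a phosphodiesterase inhibitor, at 1 micromolar, which the labels do not name for the culture medium. They were cultured for 8 h in drops of 50 microlitres holding 20 complexes. The control group had control medium of 293H cells at 0.125% by volume, the FSH/EGF group had that medium with FSH at 50 mIU/ml and EGF at 10 ng/ml, and the GDF9 group had GDF9 at 20 ng/ml. The labels name no control medium for the GDF9 group, so that comparisons with it may also differ in that medium. GDF9 is a growth factor of the TGF-beta family that oocytes secrete, FSH is a pituitary gonadotropin and EGF is epidermal growth factor. Oocytes were then removed by pipetting and RNA was taken from the cumulus cells. The labels' protocols give 8 biological replicates per condition with RNA extracted independently, and RNA of 2 replicates was pooled for each array, so that the p-values here measure the spread between such pools.

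The deposited values were on a log2 scale, from 2.916 to 14.29 over all arrays, and the authors had normalized them before deposit. RMA, Partek and GCOS are named in the submitters' processing notes without a version or a role. The genome build and the version of the array annotation are not given in the sources used here, and no coordinates are printed. The table held 35399 probe set rows. The platform annotation used here gave 1 gene symbol for 21789 rows, several symbols for 1621 rows, and did not list 11989 rows, which stay unnamed here. These may include control rows of the array, which could not be told from transcripts, and all rows were tested and counted. Of the single symbols, 21698 matched the mouse gene table through the Entrez identifier and 0 changed. Each of the 19938 genes was represented by its probe set with the highest mean signal over all 12 arrays, and 999 genes had more than 1 probe set. Arrays give no read depth, and the number of arrays limits the precision. Medians of the arrays ran from 5.41 to 5.53. No pair of arrays held identical values, and correlations between arrays of 1 group ran from 0.971 to 0.995.

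Groups were compared with limma (version 3.58.1 in R 4.3.3): a linear model with 1 mean per group over all 12 arrays, moderated variances, and Benjamini-Hochberg adjustment over all 35399 rows for each comparison, with a threshold of 0.05 on the adjusted p. All 3 pairwise comparisons were made. A change is given as a log2 difference with its standard error (SE), and counts of changes of at least 2-fold are given beside the counts of all rows past the threshold. Before the data were examined, 31 pathway lists and 7 lists of cell type markers were fixed. They were tested with camera, which compares a list with all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists. Each list was also tested with a correlation estimated from the residuals, and with fry, which asks whether its genes move 1 way on balance. The lists held 570 different genes, of which 525 were measured. The mean of a list on each array was compared between groups with a two-sided exact permutation test, whose smallest p for 4 against 4 arrays is 0.0286.

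Genes named in the text follow a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls per treatment against the control, and 5 and 5 between the treatments. These were taken among genes past the threshold whose arrays did not overlap with those of the other group. It also takes up to 4 members of each list by size of change, or the member with the smallest p where none passed, and 10 genes named in any case, of which 3 are not analysed here. Up to 4 genes changed in the same direction and up to 4 in opposite directions by both treatments were part of the rule, and 0 genes met either. Predicted genes without a proper symbol were passed over. Idi1 and Hmgcs1 under GDF9, the genes high on control array 4, and 10 gene families read from symbol prefixes were chosen after their values were seen.

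The model was tested on simulated data before use. With each row's real spread and changes placed in a small share of the rows, the GDF9 comparison called 46.3% of changes of 0.5 on the log2 scale, 89.6% of 2-fold changes and 98.5% of 4-fold changes. Alternatives tried were a variance trend, robust and no moderation, only the groups compared, array weights, removal of the 40% dimmest rows, renewed quantile normalization, equal array medians, only rows with 1 symbol, the replicate number as a block, and each array left out in turn. For the lists, an estimated correlation, fry and the mean over a gene's probe sets were tried. Leaving out control arrays 1 and 4, leaving out these and FSH/EGF array 3, and a covariate from the residuals were chosen after seeing the data.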

Results

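Gene expression was measured in mouse cumulus cells, the granulosa-derived cells that surround the oocyte, after 8 h of culture as whole cumulus-oocyte complexes. The 3 groups of 4 arrays were control medium, GDF9, and FSH with EGF (FSH/EGF). The first principal component held 59.8% of the variance and parted the 4 FSH/EGF arrays from the other 8. Correlations of FSH/EGF arrays with arrays of the other groups ran from 0.942 to 0.965, against 0.965 to 0.993 between GDF9 and control arrays. Control array 1 lay farthest from its group, with an array weight of 0.269 where the other arrays ran from 0.485 to 2.04. Control array 4 held more oocyte transcripts: the median of 22 oocyte markers was 0.95 higher on the log2 scale than on the other control arrays. On FSH/EGF array 3 it was 0.25 higher than on the other FSH/EGF arrays. The oocyte gene Padi6 stood at 7.05 on control array 4 and at 4.46 to 4.51 on the other controls.

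**Figure D1:**
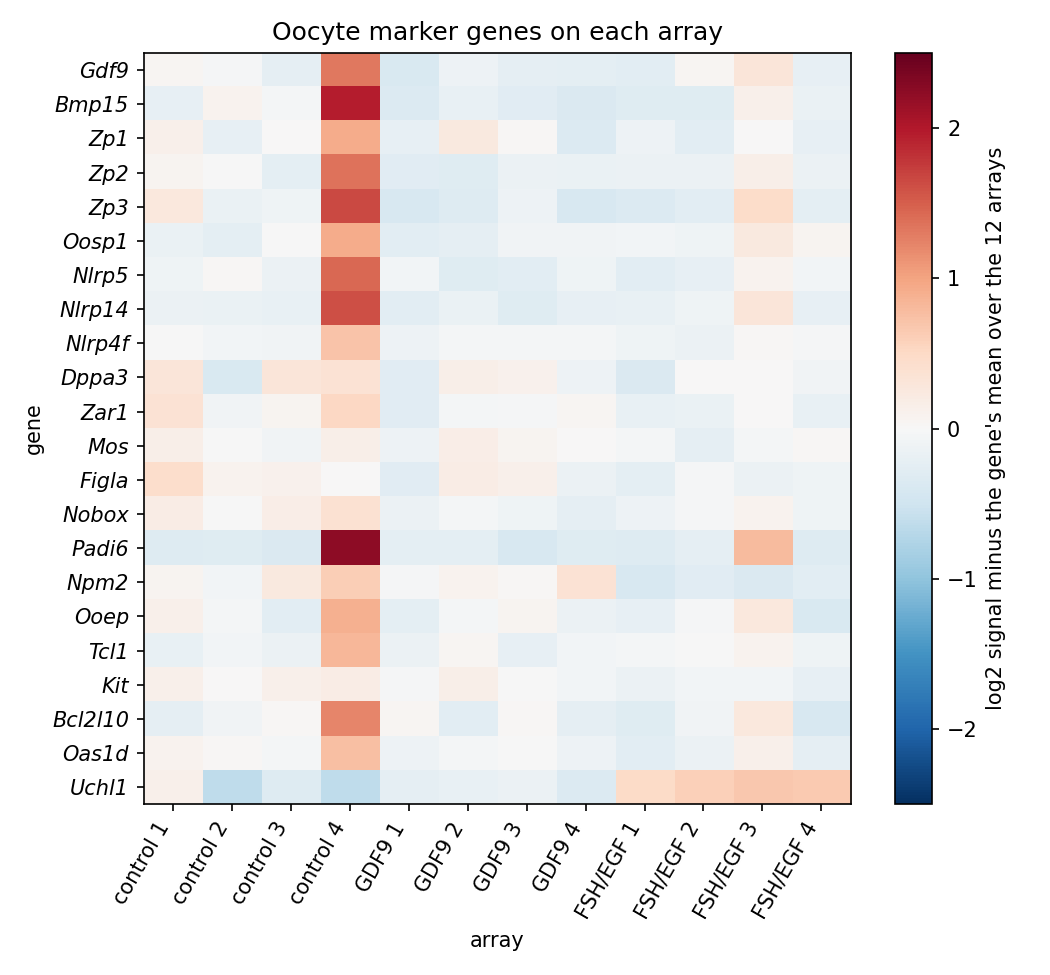
Log2 signal of 22 oocyte marker genes (vertical) on each of the 12 arrays (horizontal), each minus the gene's mean over the 12 arrays, as a colour. On control array 4, 15 markers were more than 0.5 above the other controls, and Uchl1 was higher on the FSH/EGF arrays (10.75 to 10.95) than on the others.

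FSH/EGF minus control asked which transcripts differ after exposure to the gonadotropin and growth factor that bring on cumulus expansion in culture. Several genes of the expanding matrix rose. Ptgs2, the inducible enzyme of prostaglandin synthesis, rose by 4.83 ± 0.34 (log2, SE, n = 4 and 4; 28.4-fold; limma adjusted p = 3.56e-07), and the pentraxin Ptx3 rose by 4.30 ± 0.31. Tnfaip6, whose product links hyaluronan to proteins, rose by 3.86 ± 0.27, Cd44, a hyaluronan receptor, 7.98-fold, and Has2, the hyaluronan synthase, by 2.88 ± 0.26. In the same cells the FSH receptor gene Fshr fell by 3.14 ± 0.09, to a mean of 5.26 from 8.40. Of the 14 measured genes of the cumulus expansion list, 7 rose and 2 fell, with the same counts adjusted over the list alone, and the list passed camera (mean change 1.54, adjusted p = 0.00845; adjusted p = 0.227 with an estimated correlation).

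**Figure D2:**
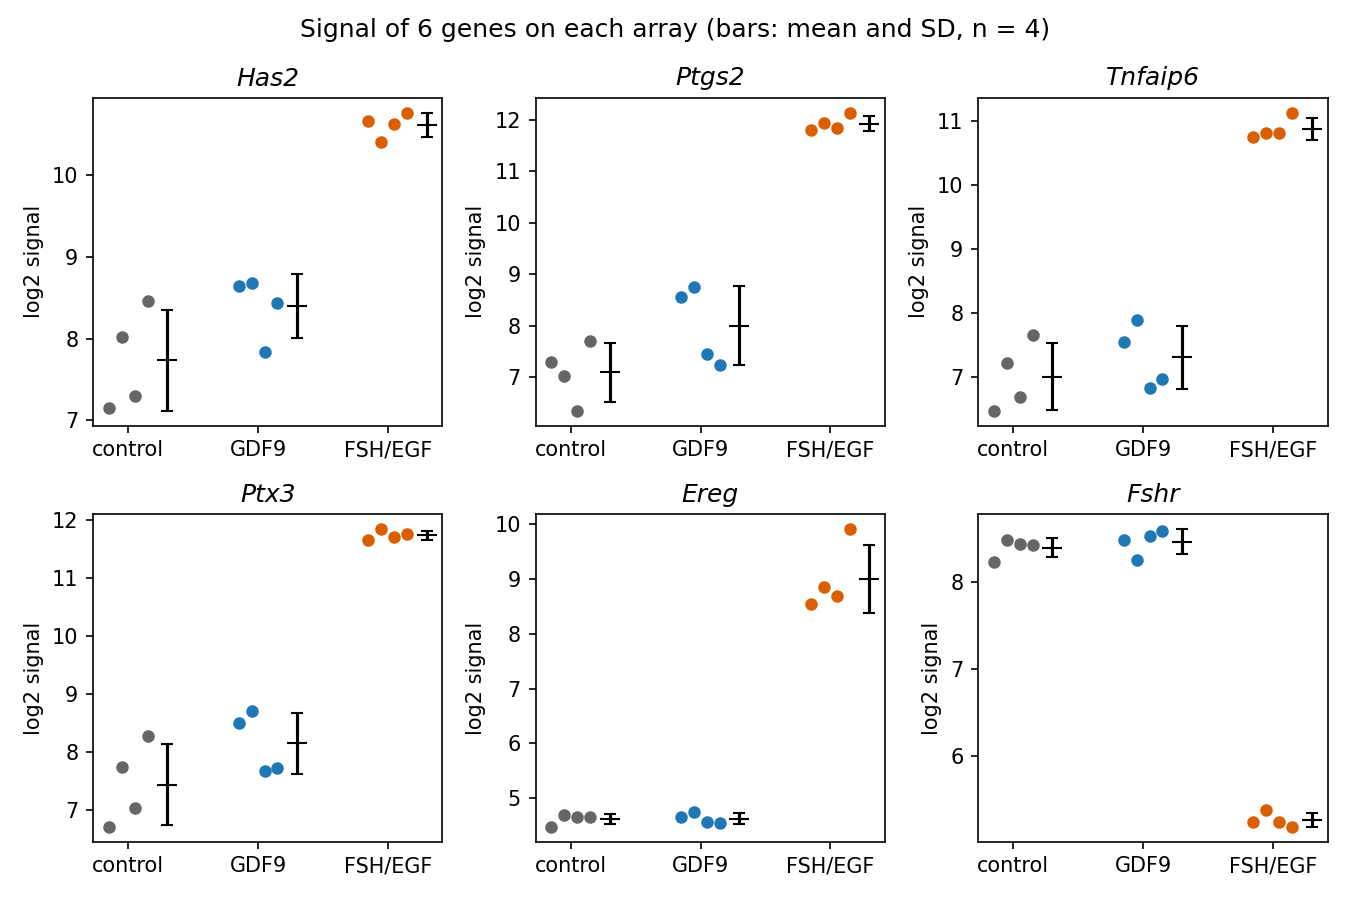
Log2 signal of 6 genes named in any case, 1 point per array, with the mean and SD of each group of 4 arrays beside the points; each vertical axis has its own range and does not start at 0. Has2, Ptgs2, Tnfaip6, Ptx3 and Ereg were higher on the 4 FSH/EGF arrays than on every other array, and Fshr was lower.

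The 8 largest rises reached from 4.83 to 6.87. The control mean of Sult1e1 was 3.80, near that of the dimmest of 10 level classes of genes (3.89), and signal over background was not analysed, so that the size of its rise is approximate. Sult1e1, an estrogen sulfotransferase, rose by 6.87 ± 0.15 (limma adjusted p = 1.58e-11), Nts, the precursor of the peptide neurotensin, by 5.73 ± 0.10, Akr1b8, an aldo-keto reductase, by 5.26 ± 0.13, and Sfrp2, a secreted Wnt-binding protein, by 5.19 ± 0.14. Flnc, an actin-binding filamin, rose by 5.15 ± 0.11, Btc, the EGF receptor ligand betacellulin, by 5.08 ± 0.09, and Nmu, the precursor of the peptide neuromedin U, by 4.95 ± 0.09; Ptgs2 completed the 8. The largest fall was that of Akr1c14, a hydroxysteroid dehydrogenase of the aldo-keto reductase family, at -4.90 ± 0.13 (limma adjusted p = 9.09e-11). Slc18a2, a vesicular monoamine transporter, followed at -4.58, then Tmem182 at -4.15, Myocd, a cofactor of smooth muscle transcription, at -4.13, Fhl1 and Cnnm1 at -3.95 each, Hpgd, which breaks down prostaglandins, at -3.93, and Grb14, an adaptor of insulin receptor signalling, at -3.82. On all 4 FSH/EGF arrays these genes lay beyond all 4 control arrays.

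Among the EGF-like ligands and their receptors, 4 of 13 rose and 1 fell (4 and 6 adjusted over the list alone). Btc rose by 5.08 and Ereg, epiregulin, by 4.37 ± 0.23, Epgn rose by 1.59, and the receptor gene Egfr fell by 2.28 ± 0.08; the list as a whole was not past camera's threshold (adjusted p = 0.605). Of the 24 genes of ERK feedback and early response, 14 rose and 3 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.000396; adjusted p = 0.356 with an estimated correlation). Ier3 rose by 4.19, Egr3, a transcription factor, by 3.09, and Dusp6 and Dusp4, phosphatases that act on MAP kinases, by 3.47 and 2.84. The list of ovulatory LH and cAMP response genes had 13 risers and 4 fallers of 22, the same adjusted over the list alone (camera adjusted p = 0.000396; adjusted p = 0.165 with an estimated correlation). Sult1e1 led it, followed by Timp1, a metalloprotease inhibitor, at 4.43 ± 0.09 and the transcription factor Cebpa at 2.56 ± 0.12.

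Most measured genes of the granulosa differentiation and granulosa lineage lists fell. In the list named for FSH-induced granulosa differentiation, 10 of 15 measured genes fell and 1 rose, also when adjusted over the list alone (mean -1.04, camera adjusted p = 4.95e-05, adjusted p = 0.0949 with an estimated correlation). Whether FSH induces each member in these cells was not tested. The list's leading members were Fshr, Igf1 at -2.48 ± 0.21, Nr5a2, a nuclear receptor, at -2.09 ± 0.10, and Hsd17b1, which reduces estrone to estradiol, at -1.94 ± 0.13. The granulosa lineage markers overlap with that list and fell in 7 of 11 cases, with 1 rise, the same adjusted over the list alone (mean -0.85; camera adjusted p = 0.00202; adjusted p = 0.0949 with an estimated correlation). Amhr2, the receptor of anti-Müllerian hormone, fell by 2.16 ± 0.13, and Inhba, the activin and inhibin beta A chain, was the riser at 1.02 ± 0.15. Steroidogenesis genes went both ways, with 4 risers and 5 fallers of 13 (5 and 5 adjusted over the list alone). Star, which carries cholesterol into mitochondria, rose by 2.02 ± 0.10 and Fdx1, an electron donor of steroid hydroxylases, by 2.20 ± 0.19, while Esr2, estrogen receptor beta, fell by 2.29 ± 0.15.

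Metabolic genes formed several of the lists past the threshold. Of the 20 measured genes of cholesterol synthesis, 17 rose and 0 fell (18 and 0 adjusted over the list alone), with a mean change of 1.02 (camera adjusted p = 6.05e-10; adjusted p = 0.165 with an estimated correlation). Idi1 rose by 1.89 ± 0.18, Cyp51 by 1.82 ± 0.19, Sqle by 1.60 ± 0.10 and Lss by 1.42 ± 0.19. Synthesis of hexosamine and hyaluronan precursors had 9 risers and 1 faller of 14 (10 and 1 adjusted over the list alone; camera adjusted p = 0.000235; adjusted p = 0.165 with an estimated correlation). Besides Has2, these included Ugdh, which makes UDP-glucuronate, at 2.76 ± 0.14, Gfpt2, which makes glucosamine 6-phosphate, at 1.84 ± 0.08 and Pgm3 at 1.34 ± 0.17. In glycolysis and glucose uptake, 8 of 16 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0397; adjusted p = 0.227 with an estimated correlation), with the glucose transporter gene Slc2a1 at 3.13 ± 0.20, hexokinase Hk2 at 1.19 and pyruvate kinase Pkm at 1.11. This last call ended when the values were quantile normalized again (adjusted p = 0.084) and when dim rows were left out (adjusted p = 0.165).

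Stress, protease and signalling lists also passed. The integrated stress and unfolded protein response list had 11 risers and 1 faller of 19 (13 and 1 adjusted over the list alone; camera adjusted p = 0.000396; adjusted p = 0.0949 with an estimated correlation), led by Ddit4 at 2.73, the chaperone gene Dnajb9 at 1.61 and Edem1 at 1.49. Heat shock and oxidative stress genes rose in 9 of 17 cases and fell in 3 (10 and 3 adjusted over the list alone; camera adjusted p = 0.00871; adjusted p = 0.165 with an estimated correlation). They were led by the glutathione transferase gene Gsta4 at 2.96, Hspb8 at 2.56, the metallothionein gene Mt2 at 2.15 and Srxn1 at 2.11. Of the 16 genes of the plasminogen system and matrix proteases, 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00341; adjusted p = 0.134 with an estimated correlation). The riser with the largest change was the inhibitor Timp1, followed by the urokinase receptor gene Plaur at 3.46 and Mmp14 at 2.24, and the protease gene Adamts5 fell by 2.94. Wnt and Notch signalling had 10 risers and 3 fallers of 19 (11 and 4 adjusted over the list alone; camera adjusted p = 0.00958; adjusted p = 0.0949 with an estimated correlation). Sfrp4, a secreted Wnt-binding protein, rose by 4.16, the Notch ligand Jag1 by 3.62 and Notch2 by 2.38, and Hey2, a Notch target, fell by 2.83. Without dim rows the heat shock, plasminogen and Wnt lists were no longer past camera's threshold (adjusted p = 0.109, 0.118 and 0.109).

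The other 26 lists were not past camera's threshold (lowest adjusted p = 0.0672). They held 104 risers and 67 fallers over 374 places (111 and 83 adjusted over each list alone), so that most held genes going both ways. In the basement membrane list 7 of 14 rose and 4 fell, with Col18a1 at 1.65; of 21 cytokine and innate immunity genes 8 rose and 1 fell, with Tlr2 at 2.85 and Stat3 at 1.80. Amino acid transporters split into 6 risers and 5 fallers of 17, with Slc7a11, the cystine transporter gene, at 2.99, Slc7a8 at 2.88, Slc38a4 at -2.38 and Slc38a5 at -2.28. Among 17 hypoxia and angiogenic genes 7 rose and 4 fell, led by Fgf2 at 2.61 and Hif1a at 2.34. Prostaglandin synthesis and response had 7 risers and 3 fallers of 14, with Ptgs2 and Hpgd at the extremes, and apoptosis regulators 7 and 3 of 21, with Xiap at 1.46. Cell cycle inhibitors rose in 5 of 13 cases, with Gadd45g at 1.73. The G1/S list had 7 risers and 4 fallers of 21, with Ccnd2, cyclin D2, at -1.92 and Pcna at 1.40, and mitosis genes 6 and 2 of 20, with Ccnb2 at -0.66. CREB target genes had 6 risers and 2 fallers of 17, with Pde4d at 2.13.

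In the TGF-beta family, receptors and SMADs had 5 risers and 5 fallers of 18, with the coreceptor gene Tgfbr3 at -2.55 ± 0.12 and Smad3 at 1.40 ± 0.12. SMAD2/3 target genes had 8 and 3 of 22, with Pmepa1 at 1.49, and BMP target genes 3 and 4 of 12, with Id1 at 1.64. Smad7, the inhibitory SMAD gene, was at -0.35 ± 0.15 (limma adjusted p = 0.113), and it was past the threshold at -0.57 after renewed quantile normalization (adjusted p = 0.0129). Of 11 genes enriched in cumulus cells, 2 rose and 4 fell, with Tnfaip6 and the carbonic anhydrase gene Car14 (-3.53) at the extremes, and Slc38a3 at -2.10. Of 8 mural granulosa genes 1 rose (Emb, 2.61) and 2 fell, and of 8 genes of natriuretic peptide and cGMP signalling, which holds meiosis in arrest, 1 rose and 2 fell, namely Nppc at 0.499 times the control and its receptor gene Npr2 at -0.72. Interferon genes had 1 riser and 1 faller of 14, with Bst2 at -1.24. For gap junctions 1 of 8 fell, Gja4 at -0.31 (limma adjusted p = 0.0263), a call lost under 8 alternatives, among them leaving out control array 4 (-0.27, adjusted p = 0.0658), FSH/EGF array 1 (-0.29, adjusted p = 0.0737) or FSH/EGF array 4 (-0.29, adjusted p = 0.0664).

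Of the marker lists of other cells, 0 passed camera. The means of the endothelial, surface epithelial, theca and red blood cell lists on the 4 FSH/EGF arrays did not overlap with the controls (exact permutation p = 0.0286 each, adjusted p = 0.0388 over the lists). This was not particular to them, since it held for 28 of the 38 lists. The endothelial and surface epithelial means were positive (0.286 and 0.474), while the medians of their members were negative (-0.0463 and -0.184). Of 12 endothelial markers 3 rose and 1 fell, with Cdh5, VE-cadherin, at 3.18; of 9 markers of ovarian surface epithelium 2 rose, the keratin genes Krt8 at 3.02 and Krt18 at 2.72, and 2 fell. Of 13 theca and stroma markers 1 rose (Mgp, 1.15) and 3 fell, among them Acta2 at -2.34. Of 13 leukocyte markers 2 rose, with Cd68 at 0.50, and 1 fell. Of 3 red blood cell markers 2 fell, with Slc4a1 at -0.31, a call lost without control array 3 (-0.25, adjusted p = 0.0614) or FSH/EGF array 1 (-0.30, adjusted p = 0.0533). Of 22 oocyte markers 1 rose and 2 fell: Uchl1 was at 0.96 and Npm2 at -0.54, and the call for Npm2 was lost without control arrays 1 and 4 and FSH/EGF array 3 (adjusted p = 0.0718). Most of these markers were raised on control array 4; without it, Npm2 stood at -0.40 and stayed past the threshold. Uchl1 was not raised on that array (9.64, other controls 9.65 to 10.41), so that its rise with FSH/EGF need not stand for oocyte RNA.

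In total, 10269 rows were past limma's threshold, 5856 higher and 4413 lower with FSH/EGF. At least 2-fold changes numbered 1818, with 1272 higher and 546 lower. Counted by gene, 7334 of 19938 genes were past the threshold, 4357 higher and 2977 lower. With equal array medians, the split moved to 6637 higher and 2588 lower, or 71.9% higher in place of 57%, and after renewed quantile normalization to 4758 higher and 4327 lower, or 52.4%. Groups did not overlap in 33.2% of rows, where chance gives 2.86%. Of the 38 lists, 12 passed camera, 10 upward and 2 downward; 0 of them passed with an estimated correlation, and 30 lists passed fry.

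GDF9 minus control asked which transcripts differ after exposure to the oocyte factor without FSH and EGF, in complexes whose own oocytes were present during culture. No row passed limma's threshold, and the smallest adjusted p was 0.847. At an unadjusted p under 0.05 there were 1590 rows, or 4.49%, and without moderated variances 0 rows passed as well. Groups did not overlap in 702 rows, or 1.98%, where chance gives 2.86%. The expansion genes named in any case showed positive differences below 2-fold, with wide errors: Ptgs2 was at 0.91 ± 0.34 (95% interval 0.17 to 1.65; limma adjusted p = 0.971), Ptx3 at 0.71 ± 0.31, Has2 at 0.67 ± 0.26 and Tnfaip6 at 0.30 ± 0.27. Ereg was at 0.01 ± 0.23, Fshr at 0.07 ± 0.09 and Smad7 at -0.11 ± 0.15. Each of these had overlapping arrays in both groups. The cumulus expansion list had a mean of 0.162, above random lists matched on mean level (middle 95% from -0.0529 to 0.0593), which were drawn after the result was seen. Of its 14 genes 5 were higher, the median was -0.0176, and the list was not past camera's threshold (adjusted p = 0.377; adjusted p = 0.825 with an estimated correlation).

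The genes of cholesterol synthesis lay higher with GDF9 as a set. All 20 measured genes had a positive difference, with a mean of 0.31, and on each of the 4 GDF9 arrays the list's mean lay above all 4 control arrays (exact permutation p = 0.0286, the smallest possible; adjusted over the 38 lists 0.858). Adjusted over the list alone 9 genes rose, against 0 over all rows. Msmo1, a methylsterol monooxygenase, was at 0.55 ± 0.10 (limma adjusted p = 0.847), Idi1 at 0.76 ± 0.18 and Hmgcs1, which makes HMG-CoA, at 0.42 ± 0.13. The list passed camera (adjusted p = 1.64e-18; adjusted p = 0.306 with an estimated correlation).

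Another 5 lists passed camera upward, with small mean changes. ERK feedback genes were at 0.15 (adjusted p = 0.00633; adjusted p = 0.825 with an estimated correlation), where 1 gene rose adjusted over the list alone and Dusp6 was at 0.78 ± 0.14 (limma adjusted p = 0.847). Mitosis genes were at 0.10 (adjusted p = 0.00633; adjusted p = 0.825 with an estimated correlation), with Ccna2, cyclin A2, at 0.23. FSH-induced differentiation genes were at 0.10 (adjusted p = 0.0238; adjusted p = 0.805 with an estimated correlation), where 2 rose adjusted over the list alone and Inhbb, the activin and inhibin beta B chain, was at 0.54 ± 0.11. Hexosamine synthesis was at 0.12 (adjusted p = 0.0315; adjusted p = 0.805 with an estimated correlation), with Ugp2 at 0.25, and G1/S genes at 0.06 (adjusted p = 0.0491; adjusted p = 0.805 with an estimated correlation), with Mcm4 at 0.27. Oocyte markers passed downward at -0.32 (adjusted p = 5.05e-07; adjusted p = 0.805 with an estimated correlation), with Nobox at -0.31; without control array 4 they were at -0.09 (adjusted p = 0.0778). Random lists matched on mean level, drawn after the result was seen, covered the means of mitosis (middle 95% from 0.00391 to 0.119), FSH-induced (0.00307 to 0.115) and G1/S genes (-0.0229 to 0.0869). Those for hexosamine synthesis (-0.0283 to 0.105), ERK feedback (-0.0133 to 0.0844) and oocyte markers (-0.0811 to -0.00185) did not. Among the 31 lists not past the threshold, 2 members rose adjusted over their list alone, Inhbb in the SMAD2/3 target and in the mural granulosa list, and granulosa lineage markers had a mean of -0.01, with Inhba at 0.52 ± 0.15.

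Except for cholesterol synthesis, each of these lists lost its call when some array was left out. Without control array 1 the adjusted p was 0.516 for mitosis, 0.246 for FSH-induced genes, 0.81 for hexosamine synthesis and 0.0507 for G1/S. Without control array 3 it was 0.3 for ERK feedback, 0.0544 for hexosamine synthesis and 0.325 for G1/S, and without control array 2 it was 0.0586 for ERK feedback. The G1/S list also lost its call without control array 4 (0.107). A lost call does not by itself show that the mean change rested on the array left out. Relative to the mean of the controls, G1/S stood at 0.010 on control array 4, while mitosis stood at -0.219 on control array 1. Without GDF9 array 1 the adjusted p was 0.216 for each of FSH-induced genes, hexosamine synthesis and G1/S. Without GDF9 array 2 it was 0.0556 for ERK feedback and 0.142 for G1/S, without GDF9 array 3 it was 0.276 for mitosis and 0.19 for G1/S, and without GDF9 array 4 it was 0.151 for ERK feedback and 0.0968 for hexosamine synthesis. Dusp6 was past limma's threshold without GDF9 array 3, at 0.95 (adjusted p = 0.0103), the 1 row called in any of these fits.

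**Figure D3:**
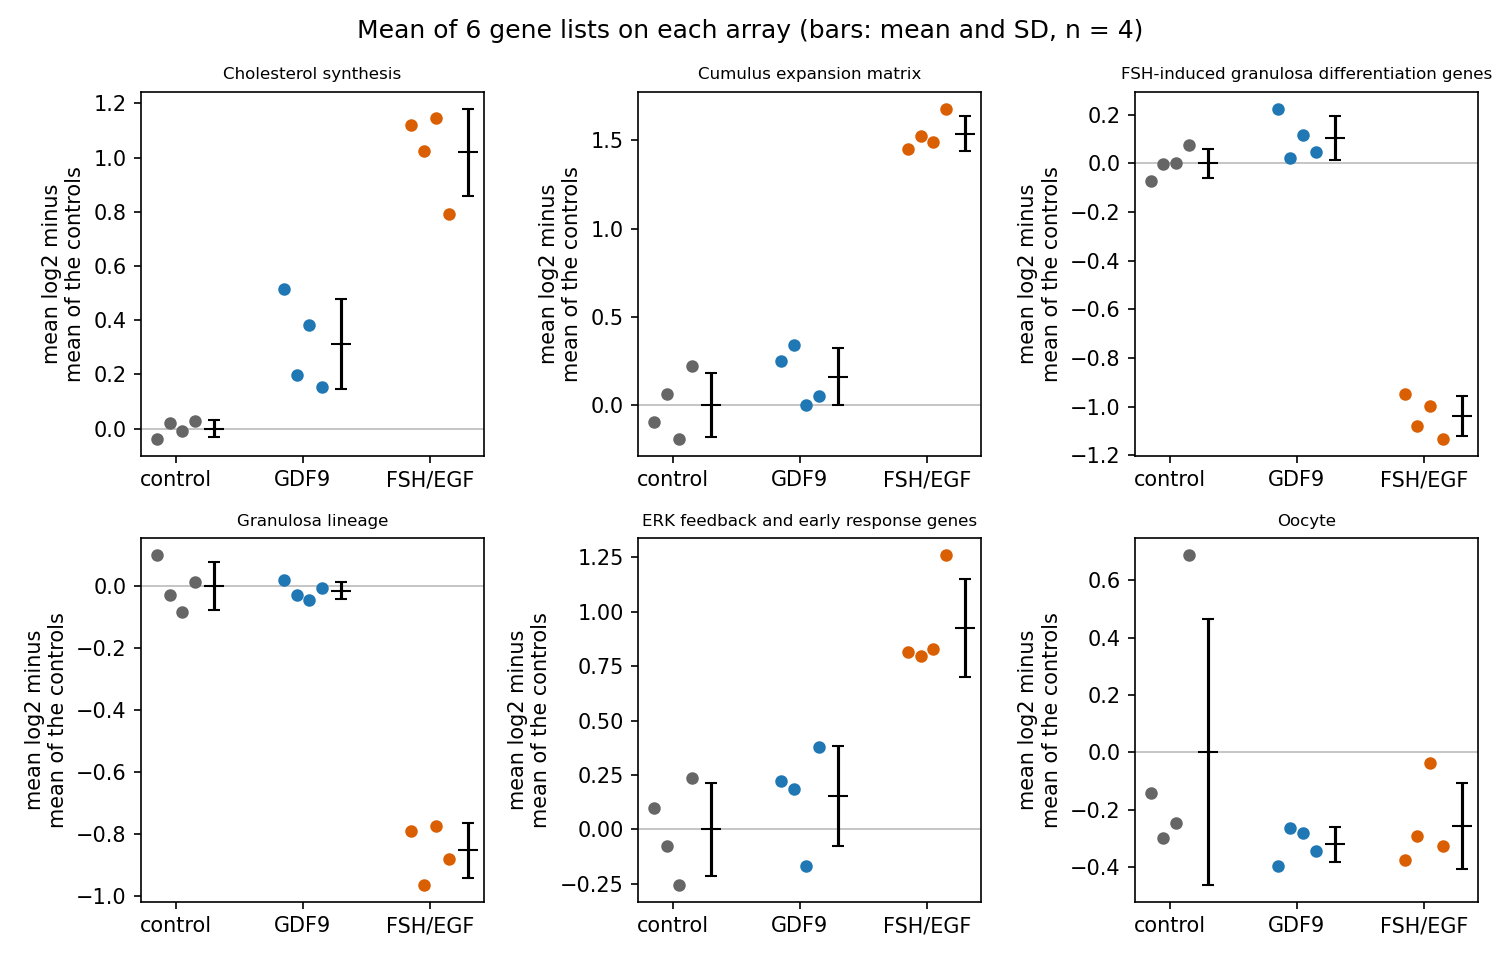
Mean log2 signal of 6 gene lists on each array, minus the mean of the 4 control arrays, with the mean and SD of each group of 4 arrays beside the points; vertical axes differ in range. Cholesterol synthesis lay at 0.155 to 0.515 on the GDF9 arrays and at -0.039 to 0.028 on the control arrays, and the oocyte markers stood at 0.689 on control array 4 alone.

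FSH/EGF minus GDF9 compared the treatments directly. The largest differences were those found against the control: Sult1e1 was higher with FSH/EGF by 6.84 ± 0.15 (limma adjusted p = 1.64e-11), Nts by 5.70, Sfrp2 by 5.31, Flnc by 5.17 and Akr1b8 by 5.12. Akr1c14 was lower at -4.76 ± 0.13, Slc18a2 at -4.60, Tmem182 at -4.19, Myocd at -4.18 and Hpgd at -3.91. Expansion genes were higher with FSH/EGF than with GDF9: Ptgs2 by 3.92 ± 0.34, Ptx3 by 3.60 ± 0.31, Tnfaip6 by 3.56 ± 0.27 and Has2 by 2.22 ± 0.26. Ereg was higher by 4.36, Fshr lower at -3.22 and Smad7 at -0.24 ± 0.15 (limma adjusted p = 0.327). Inhbb was at -1.43 ± 0.11 (limma adjusted p = 9.9e-07), with a mean of 10.44 with GDF9, 9.91 in the control and 9.01 with FSH/EGF.

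Cholesterol synthesis was also higher with FSH/EGF than with GDF9, in 16 of 20 genes with 0 lower (17 and 0 adjusted over the list alone; mean 0.71; camera adjusted p = 3.23e-07; adjusted p = 0.223 with an estimated correlation), with Cyp51 at 1.39, Sqle at 1.24, Idi1 at 1.12 and Lss at 1.11. In all, 13 lists passed camera, 11 upward and 2 downward, and 3 of them passed with an estimated correlation: FSH-induced differentiation genes (1 higher and 9 lower of 15), granulosa lineage markers (1 and 7 of 11), and the stress response list (12 and 1 of 19), each at an adjusted p = 0.0483 with an estimated correlation. Cytokine and innate immunity genes passed here (7 higher and 0 lower of 21; camera adjusted p = 0.0204; adjusted p = 0.397 with an estimated correlation), with Tlr2 at 3.06, Stat3 at 1.63 and Myd88 at 1.39. The basement membrane list passed too (8 and 4 of 14; camera adjusted p = 0.0296; adjusted p = 0.237 with an estimated correlation), with Col18a1 at 1.70, and lost the call without GDF9 array 3 (adjusted p = 0.0534). Its mean of 0.492 lay inside the middle 95% of random lists matched on level (-0.245 to 0.508). In total 7979 rows were past limma's threshold, 4806 higher and 3173 lower (60.2% higher; 53% after renewed quantile normalization and 66.9% with equal array medians), and 1598 of them changed at least 2-fold, 1039 higher and 559 lower; by gene, 5804 passed.

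Between the treatments, 0 rows were past the threshold in both. Over all rows the log2 changes of GDF9 and FSH/EGF against the shared controls correlated at 0.356, across genes, which are not independent replicates. Unchanged groups simulated against simulated controls, shared in the same way, gave 0.499. The covariance was 0.0257 against a simulated 0.0113, a difference of 0.0144. The simulation drew independent noise for each row and array and no effect of either treatment. It holds no deviations that span many rows of an array, so that neither gap can be read as a shared response. With the controls split into separate pairs for each treatment, the correlation ran from -0.0313 to 0.179, with a median of 0.129, over 6 splits. The covariance then ran from -0.00317 to 0.0165. Of the 1818 rows changed at least 2-fold by FSH/EGF, 68% had the same sign with GDF9, and 59.3% to 72.3% with split controls. By mean level of the genes, the median changes of both treatments were negative in classes 1 to 6 of 10 and positive in classes 7 to 10. Signs shared through this pattern were not removed from these shares.

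**Figure D4:**
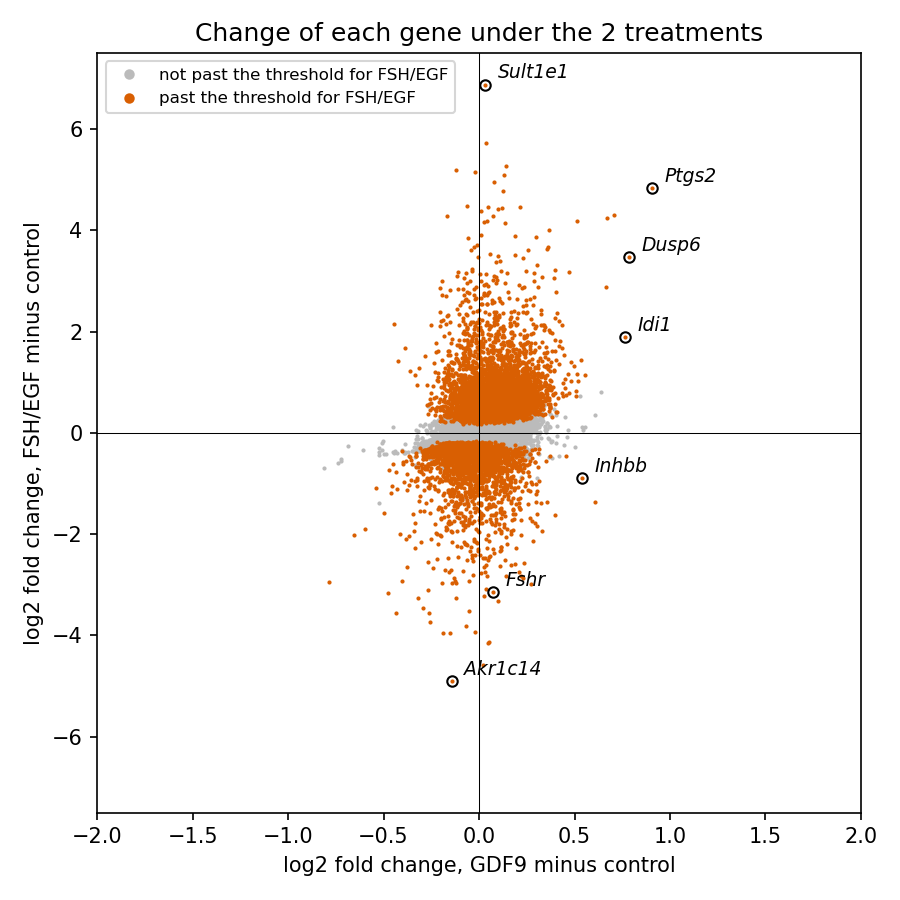
Log2 fold change of each gene with GDF9 (horizontal) and with FSH/EGF (vertical), each minus the shared control arrays, as means of 4 arrays; the axes have different scales, and orange marks genes past the threshold for FSH/EGF. Sult1e1 stood at 6.87 with FSH/EGF, Dusp6 at 0.78 with GDF9 and 3.47 with FSH/EGF, and Inhbb at 0.54 and -0.89.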

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

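The tests of a single deviating array for GDF9, of an array-wide deviation for the oocyte markers, all 3 tests for the cholesterol list, and the count of splits for the GDF9 rows were chosen only after the result was seen; the fits without control arrays 1 and 4 and with a residual covariate were added later.

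In 16 of 369 groups of 4 arrays, 1 array stood far from the other 3, where chance gives about 1 in 20 groups, or 18.4. FSH/EGF array 4 was high for Tnfaip6 (11.13, others 10.76 to 10.81), Tgfbr3 (5.68, others 5.40 to 5.42) and Fgf2 (7.81, others 7.62 to 7.63). It was also high for the means of ERK feedback genes (1.26, others 0.80 to 0.83), plasminogen system genes (0.99, others 0.81 to 0.84) and cytokine genes (0.64, others 0.35 to 0.38), each minus the control mean. Control array 1 was low for Esr2 (9.96, others 10.57 to 10.62), Lss (6.03, others from 6.48 up), Hif1a (8.48, others 8.77 to 8.82) and the mean of mitosis genes (-0.22, others 0.04 to 0.09), and high for Mt2 (6.88, others 5.84 to 6.01). Control array 4 was high for Gja4 (5.47, others 5.29 to 5.31) and the mean of oocyte markers (0.69, others -0.30 to -0.14). Fhl1 was low on FSH/EGF array 1 (5.32, others 5.50 to 5.52), Nr5a2 was high on GDF9 array 4 (9.29, others 9.02 to 9.06) and Hsd17b1 on GDF9 array 1 (11.96, others 11.61 to 11.66).

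Oocyte markers on control array 4 were 0.95 higher in the median than on the other controls, and 15 of 22 were more than 0.5 higher. RNA of oocytes left after pipetting would raise the same genes outside the list on FSH/EGF array 3, the other array with raised markers: of 20 genes over 1 higher on control array 4, 17 were higher there, with a median of 0.211 where random lists matched on level gave -0.06 to 0.05. They were not chosen as oocyte genes: beside Rfpl4 (2.23 on control array 4, 0.67 on FSH/EGF array 3) and Btg4 (1.35, 0.45) they held Dusp1 (1.22, -0.75) and Penk (1.20, -0.11). A deviation of the whole array is argued against by random lists matched on level, whose medians on control array 4 were at -0.137 to 0.007 (middle 95%), which leaves 1.01 for the markers. As a hypothesis, carried-over oocyte RNA may account for the 15 markers raised by more than 0.5, but not for every gene high on control array 4. Markers such as Figla (5.32, other controls 5.39 to 5.74) were not raised. Explanations beyond carried-over RNA and a deviation of the whole array were not tested.

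No row passed for GDF9 minus control. That 1 deviating array hid the changes is argued against by the fits leaving out each array, which called at most 1 row. A fit with the first residual component as a covariate called 0 rows. That component ran from -2.29 to 1.08 on the control arrays and from -0.981 to 1.36 on the GDF9 arrays. On the FSH/EGF arrays it ran from -0.393 to 0.267, so that it was not shared evenly by all groups. Taken from residuals, it can lower the spread within groups but cannot change a group difference. Variation that goes with the groups, or lies in other components, therefore stays open. The simulation called 89.6% of 67 changes of 2-fold, placed together with 67 of 0.5 and 66 of 2 on the log2 scale. For rows drawn at random, this argues against too few arrays where that many rows change. Where fewer rows change, the adjustment asks for a smaller p. The simulation therefore does not answer for a few isolated 2-fold changes. Of changes of 0.5 on the log2 scale it called 46.3%, so that changes of that size may have gone unseen. The simulation does not answer for rows with a wide spread, such as Ptgs2. On the real arrays 6 rows differed by at least 2-fold at any p, the largest by 1.78 on the log2 scale, and 0 of them were called. Whether the oocytes in the complexes already supplied GDF9 was not tested.

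The mean of the cholesterol synthesis list was higher on all 4 GDF9 arrays than on every control array. The array-wide deviation of control 1 and GDF9 1 is argued against by the difference without both, 0.232 of 0.312 with the groups still apart, and oocyte RNA in control 4 by the difference of 0.321 without it. A wider signal range that lifts abundant genes is argued against by random lists matched on level, which had a mean of 0.06 (95% from 0.01 to 0.11) and left 0.253. What stays open is chance, since the exact p of 0.0286 became 0.858 when adjusted over 38 lists and camera gave an adjusted p of 0.306 with an estimated correlation. A difference in the control medium also stays open, since the labels name none for the GDF9 group. As a hypothesis from these same data, GDF9 may raise the transcripts of this pathway by a small amount.

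Other groupings of the same arrays bear on the counts. For FSH/EGF minus control, 1 of 35 splits, the real one, gave as many rows (10269, highest other 0), and likewise for rows changed at least 2-fold (1 split; 1818, highest other 0). FSH/EGF minus GDF9 had 1 split with as many rows (7979, highest other 0) and 1 with as many 2-fold rows (1598, highest other 0). For each of these 4 counts, 1 of 35 is the smallest share that the splits can give. Splits that mix FSH/EGF arrays with the others widen the spread within groups, so that their counts of 0 do not measure chance. For GDF9 minus control the real counts of rows and of 2-fold rows were 0, which all 35 splits reach by construction, so that the comparison says nothing about chance there; the highest other counts were 920 and 28. The split with 920 rows put control arrays 1 and 3 with GDF9 arrays 2 and 3, which points to a structure of the arrays across the groups. For the lists, 6 splits gave at least the 7 lists called for GDF9 (highest other 11), so that chance is not excluded for that count. For FSH/EGF minus control, 2 splits gave at least the 12 lists called (highest other 13). The split with 13 put control array 1 with FSH/EGF arrays 1, 2 and 4. Such a split still holds much of the treatment difference, so that these list counts neither measure nor exclude chance. For FSH/EGF minus GDF9, 1 split, the real one, gave the 13 lists (highest other 11). That margin leaves chance open, since 3 list counts were tried and these splits mix the arrays too.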

How the results depend on the processing

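Counts of rows past the threshold stayed within 1.5 times under the alternatives run for both FSH/EGF comparisons, 2-fold counts included. For GDF9 minus control they stayed at 0 under every alternative but 1: without single arrays the count was 0 to 1, the 1 being Dusp6 without GDF9 array 3, and with it the overlap with the FSH/EGF calls was 0 to 1. Leaving out 1 array gave 8139 to 10247 rows for FSH/EGF minus control and 6679 to 8152 for FSH/EGF minus GDF9. Without control arrays 1 and 4, a choice made after seeing the data, FSH/EGF minus control had 8628 rows, and 7163 without FSH/EGF array 3 too; with the residual covariate, also chosen later, it had 13653 and FSH/EGF minus GDF9 10282.

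Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.389 to 0.221, over 0.1 in 6 of 12 pairs, and 3 of 12 arrays correlated best with their own number. With the number as a block the counts were 0, 9600 and 7547 rows.

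The number of lists depended most on the test. For GDF9 the 7 lists became 0 with an estimated correlation and 0 with fry, 2 without dim rows, 3 after renewed quantile normalization, and 3 without control arrays 1 and 4, with or without FSH/EGF array 3; leaving out single arrays gave 4 to 6. In a second form of fry, which counts changes in either direction, cholesterol synthesis and SMAD2/3 target genes passed for GDF9 (fry adjusted p = 0.0498 each). For FSH/EGF minus control 12 lists became 0 with an estimated correlation and 30 with fry, and for FSH/EGF minus GDF9 13 became 3 and 31. The cause was not tested. The correlation of the treatments' changes was 0.269 to 0.427 without single arrays, lowest without GDF9 array 1 and highest without control array 4; the cause was not tested.

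Among the named genes, 347 of 356 values for GDF9, 2067 of 2079 for FSH/EGF minus control and 546 of 546 for FSH/EGF minus GDF9 kept their direction and side of the threshold. In all, 11 calls of Gja4, Slc4a1 and Npm2 were lost. For GDF9 no row was past the threshold, so that the side was nearly fixed beforehand. Many FSH/EGF genes were named for large changes past the threshold, so that these shares do not speak for calls at large. Without single arrays, the GDF9 values ran from 0.106 to 0.513 for Tnfaip6, 0.472 to 0.907 for Has2, 0.461 to 0.985 for Ptx3, 0.658 to 1.16 for Ptgs2 and 0.018 to 0.142 for Fshr. Ereg under GDF9 ran up to 0.0396 without GDF9 array 4 and changed sign to -0.0526 with array weights, -0.0366 without control array 1, -0.0296 without GDF9 array 2 and -0.042 without control arrays 1 and 4, with or without FSH/EGF array 3. Smad7 under GDF9 ran down to -0.208 without GDF9 array 1 and changed sign to 0.0263 without control array 4 and 0.0302 in both fits without control arrays 1 and 4. The cause was not tested. Signal over background was not analysed here, so that changes of dim genes carry an unknown limit.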

Other observations

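Gene families read from symbol prefixes were chosen after the data were seen. With FSH/EGF, 33 of 39 proteasome subunit genes rose and 3 fell, with a mean change of 0.566 (camera adjusted p = 1.45e-08 over the families; adjusted p = 0.295 with an estimated correlation). Of 16 aminoacyl-tRNA synthetase genes 12 rose and 0 fell, with a mean of 0.62 (camera adjusted p = 8.74e-06; adjusted p = 0.295 with an estimated correlation). Of 17 genes of the COPI and COPII vesicle coats 11 rose and 1 fell, with a mean of 0.422 (camera adjusted p = 0.000425; adjusted p = 0.295 with an estimated correlation), inside the middle 95% of random lists matched on level (-0.197 to 0.552). Of 50 genes of cytosolic ribosomal proteins 22 fell and 0 rose, with a mean of -0.303 (camera adjusted p = 3.84e-06; adjusted p = 0.295 with an estimated correlation).

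With GDF9, 0 genes of these families were past the threshold, but the means were positive for the proteasome (0.128, with 36 of 39 genes higher; camera adjusted p = 3.97e-08; adjusted p = 0.145 with an estimated correlation), the synthetases (0.153, 16 of 16 higher; 5.49e-06; 0.195) and the vesicle coats (0.12, 14 of 17 higher; 1.17e-05; 0.145). So they were for complex I subunits (0.119, 30 of 34 higher; 1.14e-07; 0.145), mitochondrial ribosomal proteins (0.0863, 60 of 74 higher; 1.14e-07; 0.145) and chaperonin subunits (0.149, 8 of 9 higher; 0.000133; 0.145). These means depended on single arrays: that of the proteasome was 0.0782 without GDF9 array 1, and without control array 1 those of the synthetases, the coats and the chaperonin were 0.0634, 0.066 and 0.0705. Ribosomal protein genes were at 0.064 with GDF9, where random lists matched on level had a mean of 0.0632, and at 0.0305 without GDF9 array 3.

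The FSH/EGF means of these 4 families kept their sign under other scalings and moved in size. After renewed quantile normalization they were 0.389 for the proteasome, 0.402 for the synthetases, 0.232 for the vesicle coats (7 rose, 2 fell) and -0.359 for ribosomal proteins. With equal array medians they were 0.643, 0.697, 0.499 and -0.226. Of the other families, complex I subunits went from 0.0133 as deposited to -0.175 after renewed quantile normalization (2 fell became 12), and mitochondrial ribosomal proteins from 0.227 to 0.0674. Olfactory receptor genes, 1015 genes with no known role in these cells, were at -0.0966 as deposited (61 fell), -0.0522 after renewed quantile normalization (20 fell) and -0.0196 with equal medians (13 fell).

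With genes in 10 classes by mean level, the median FSH/EGF change as deposited was negative in classes 1 to 6 (-0.158 in class 5) and positive in classes 7 to 10 (0.237 in class 10). Renewed quantile normalization brought these to -0.0891 and 0.0306, and equal medians to -0.0807 and 0.314. The upper quartile of the deposited values ran from 7.184 to 7.22 on the FSH/EGF arrays and from 6.967 to 7.073 on the control arrays, and whether this difference came from the treatment or from the processing was not tested.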
